A study of Homo sapiens with 6 samples.

How the data were processed

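The data were 6 Affymetrix expression arrays of MDA-MB-231 cells, 3 after transfection with pre-miR-145 and 3 after transfection with a negative control pre-miRNA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit and biotinylated cRNA was made by the standard Affymetrix protocol. The deposited values were made with RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays by quantiles and summarises probes by median polish. The version and annotation used for that step are not given in the sources used here. The log base is not stated, and the deposited values were taken as log2 values here because RMA returns those. In all 54675 rows the median of the 6 values was 0 within 1e-06, so each probe set had also been centred across the arrays. Centring leaves differences between arrays as they were and removes expression levels, so signal over background could not be judged. RMA compresses differences of dim probe sets, and cross-hybridizing probes can add other transcripts to a value.

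Probe sets were named through the array annotation given with the series. Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 several and 11721 none in that table. Through gene identifiers 41037 of the named probe sets were matched to the reference gene table, with 0 symbols changed. Control probe sets and those with several or no symbols were left out of the gene tests. Among the 13522 probe sets with several or no symbols, tested alone with limma, 0 passed the threshold and 385 had an unadjusted p below 0.05. The gene value was the mean of the probe sets of a gene, and 10523 of the 19775 genes had more than 1 probe set. The plan had been to use the probe set with the highest level, which centred values do not allow. The mean had been listed as an alternative before the data were examined, and it was taken as the main value before any test was run but after the centred values and the largest raw differences between the groups had been seen.

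Groups were compared, pre-miR-145 minus control, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided, 4 residual degrees of freedom, 4.48 prior degrees of freedom and a prior SD of 0.0975). Benjamini-Hochberg adjustment was over all 19775 genes with a threshold of 0.05. The 28 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, beside camera with an estimated correlation and beside fry. The preset correlation gave 5 lists past the threshold and fry 1, while the estimated correlation gave 0, with 1 list at an unadjusted p below 0.05. With an estimated correlation camera uses only the 4 residual degrees of freedom, so its calls differ from those at the preset for that reason too. For each list the members were also adjusted over the list alone. The genes named were *FSCN1*, all genes past the threshold in a direction with fewer than 10, up to 4 members past the threshold per list, and otherwise the 2 members with the smallest p. Genes named outside that rule were chosen after their values were seen, and the text says so. A second single gene of the plan is not analysed here. The planned test of seed matches in 3′ untranslated regions was not run, since no transcript sequences were used here.

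The alternatives were a trend or robust setting in eBayes, every probe set as a row (for which the probe set with the smallest p stands for a gene), array medians subtracted, a further quantile normalization, array weights, the replicate number as a block, probe sets ending in _x_at or _s_at left out, stricter thresholds, and each array left out in turn. Because the values are centred, the trend setting follows the mean of centred values and not abundance. The *ACTB* 3′ minus 5′ difference as a covariate was added after seeing the data. The gene test was tested on simulated data with 19775 genes and 3 against 3 arrays. It recovered 66% of log2 changes of 0.5 and 96% of log2 changes of 1, with 9 calls among unchanged genes. In it 200 genes were changed, 100 by each size. Recovery after Benjamini-Hochberg adjustment depends on how many genes change, so these shares need not hold for data in which 7 genes passed. In the simulated list test 1 list shifted by 0.2 was called and 0 others. Both simulations drew genes independently and with equal spread on all arrays. The measured lists had estimated correlations up to 0.383, so the simulation does not show how often camera calls unshifted lists here. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.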

Results

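Messenger RNA was profiled on 6 Affymetrix arrays from MDA-MB-231 cells, an established human line of triple-negative breast cancer with mesenchymal features. Cells on 3 arrays had been transfected with a precursor of miR-145, and cells on the other 3 with a negative control precursor that serves as the reference for the transfection itself. The series describes the replicates of each group as independent. It does not say more about how they were kept apart, so the p-values measure the spread between these arrays, which may be technical. The table held 54675 probe sets, of which 41091 carried 1 gene symbol, and these gave 19775 genes. Values were log2 values relative to the median of the 6 arrays for each probe set, with the log base taken from the named method. They show differences between arrays and hold no expression level. Mature miR-145 was not measured by these probe sets, so the transfection itself could not be checked in the values. The number of arrays limits the precision of every estimate.

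The comparison of pre-miR-145 with the negative control asked which genes miR-145 regulates in these cells. With pre-miR-145, 4 genes fell and 3 rose. *ABHD17C*, which encodes a protein depalmitoylase, was 2.16-fold lower, *UNG*, the uracil-DNA glycosylase of base excision repair, and *ABRACL* were each 1.73-fold lower, and *PODXL*, the cell surface sialomucin podocalyxin, was 1.55-fold lower. The 3 genes that rose encode parts of the contractile machinery. *ACTG2*, the gamma actin of smooth muscle, was 1.71-fold higher, *TAGLN*, the actin-binding protein transgelin, 1.68-fold higher, and *MYL9*, a regulatory light chain of myosin II, 1.47-fold higher.

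*ABHD17C* had a mean of 0.58 ± 0.066 on the control arrays and −0.53 ± 0.034 on the pre-miR-145 arrays (SD, n = 3 each). Its log2 fold change was −1.11 ± 0.065 (SE), with an adjusted p of 0.00138 in limma. *ABRACL* had a log2 fold change of −0.79 ± 0.070 and an adjusted p of 0.010, *UNG* −0.79 ± 0.082 and 0.0240, and *PODXL* −0.63 ± 0.064 and 0.0240. Among the genes that rose, the log2 fold changes were 0.78 ± 0.067 for *ACTG2* and 0.74 ± 0.064 for *TAGLN*, both with an adjusted p of 0.010, and 0.56 ± 0.060 for *MYL9*, with an adjusted p of 0.0289. For each of these 7 genes the 3 arrays of one group lay on one side of the 3 arrays of the other.

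The means over probe sets hid a disagreement within the 3 genes that rose. A probe set of *ACTG2* gave a log2 fold change of 1.55, or 2.94-fold, and the other *ACTG2* probe set gave −0.0019. For *TAGLN*, the 3 probe sets gave 1.2, 1.05 and −0.0097, and for *MYL9* they gave 1.00 and 0.12. With every probe set tested on its own, *ACTG2*, *TAGLN*, *MYL9*, *ABHD17C* and *ABRACL* passed the threshold, while *UNG* and *PODXL*, with 1 probe set each and so the same log2 fold changes of −0.79 and −0.63, had adjusted p-values of 0.103 and 0.109. *ABHD17C* and *ABRACL* also had 1 probe set each. None of the genes called lower could therefore be compared between probe sets.

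*FSCN1*, which encodes the actin-bundling protein fascin and is a reported miR-145 target, was 1.83-fold lower with pre-miR-145. Its mean was 0.41 ± 0.14 on the control arrays and −0.47 ± 0.18 on the pre-miR-145 arrays (SD, n = 3 each), with no overlap between the groups. The log2 fold change of −0.87 ± 0.109 had an adjusted p of 0.0732 in limma and so missed the threshold over all genes. Its probe sets gave −0.86 and −0.89, and the first of these passed in the fit of single probe sets with an adjusted p of 0.0276. With array weights in limma, *FSCN1* passed as a gene too, with an adjusted p of 0.00466. It also passed with the trend setting of limma (0.00726), which here follows the mean of centred values and not abundance. Its adjusted p ranged from 0.00466 to 0.689 over all settings.

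**Figure D1:**
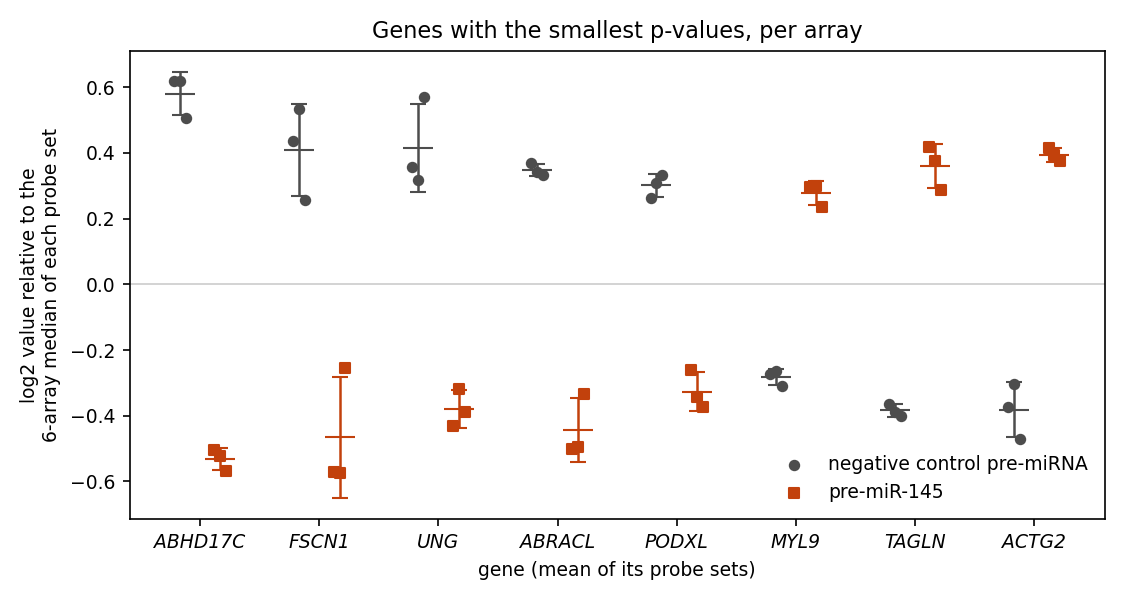
Log2 value of 8 genes on each array, relative to the median of the 6 arrays and averaged over the probe sets of the gene, with grey circles for the negative control, orange squares for pre-miR-145, and bars for the mean and SD of 3 arrays. The groups do not overlap in any of the 8 genes, and *FSCN1* has the widest spread within the pre-miR-145 arrays (SD 0.18), with replicate 3 at −0.25.

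Over all 19775 genes, 934 had an unadjusted p below 0.05 (478 lower and 456 higher), against 988.75 expected by chance. The groups did not overlap in 2051 genes, or 10.4%, where chance gives 10%. At least 1.5-fold differences, whatever their p, were seen in 11 genes, 7 lower and 4 higher. At an adjusted p below 0.25 there were 15 lower and 3 higher genes. Leaving out any array also takes a degree of freedom, and the count of 7 genes fell each time. It was 1 without control replicate 1, control replicate 2, pre-miR-145 replicate 1 or pre-miR-145 replicate 2, 2 without pre-miR-145 replicate 3, and 5 without control replicate 3, with *ABHD17C* called each time and all 7 directions kept.

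Of the 50 miR-145 targets listed from the literature, 44 were measured, and 22 were lower and 22 higher with pre-miR-145. None passed the threshold over all genes in limma, while 8 had an unadjusted p below 0.05, all of them lower. Adjusted over the list alone, 6 fell and none rose. These were *FSCN1*, *SWAP70*, which encodes a guanine nucleotide exchange factor bound to F-actin (log2 fold change −0.48), *RTKN* (−0.42), the calcineurin subunit gene *PPP3CA* (−0.28), the Src family kinase gene *YES1* (−0.29) and *SRGAP1* (−0.24). The 4 last of these were chosen for naming after their values were seen. The mean log2 fold change of the list was −0.067 and its median −0.00015, so the shift lay in a few members. The camera test gave the list an adjusted p of 0.0339, and an adjusted p of 0.825 with an estimated correlation. Without control replicate 1 the mean was −0.040 and the adjusted p 0.589, and without pre-miR-145 replicates 1 and 2 the adjusted p was 0.110 and 0.157 at means of −0.061 and −0.062.

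The list of smooth muscle contractile genes shifted upwards, for the most part through 3 members. Of 20 measured, 16 were higher, and *ACTG2*, *TAGLN* and *MYL9* passed the threshold over all genes and adjusted over the list alone. The mean log2 fold change was 0.14 and the median 0.051, and the other 17 members had a mean of 0.039. The list had an adjusted p of 0.000117 with camera and 0.00451 with fry, but an adjusted p of 0.207 with an estimated correlation (0.00738 unadjusted). That estimate was −0.0099, below the preset 0.01, so a higher correlation between the members does not account for the lost call. With an estimated correlation camera uses only the 4 residual degrees of freedom, which raises the p of the same statistic. *TPM1* (0.20), *TGFB1I1* (0.27) and *CALD1* (0.23), named after their values were seen, were higher with adjusted p-values from 0.922 to 1.00, and *ACTA2*, the alpha actin of smooth muscle, likewise named after its value was seen, had a log2 fold change of −0.15. When probe sets with names ending in _x_at or _s_at were left out, the mean of the list was 0.048 and its adjusted p 0.385. *TAGLN* and *MYL9* then kept only their probe sets at −0.0097 and 0.12. *ACTG2* was unchanged at 0.78 and still passed over all genes in limma, with an adjusted p of 0.0152.

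Genes of the actin cytoskeleton and motility list were also higher on balance. Of 49 measured, 39 were higher, with a mean log2 fold change of 0.056 and a camera adjusted p of 0.000376, or an adjusted p of 0.765 with an estimated correlation. *MYL9* passed over all genes, and *MYL9* (higher) and *FSCN1* (lower) adjusted over the list alone. *MYH9*, the heavy chain of nonmuscle myosin IIA, named after its value was seen, had a log2 fold change of 0.28 and an adjusted p of 0.761. Without the _x_at and _s_at probe sets the adjusted p of the list was 0.0992, and without control replicate 3 its mean was 0.031. With the *ACTB* 3′ minus 5′ difference of each array as a covariate, chosen after seeing the data, its mean was 0.030 and its adjusted p 0.0492.

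**Figure D2:**
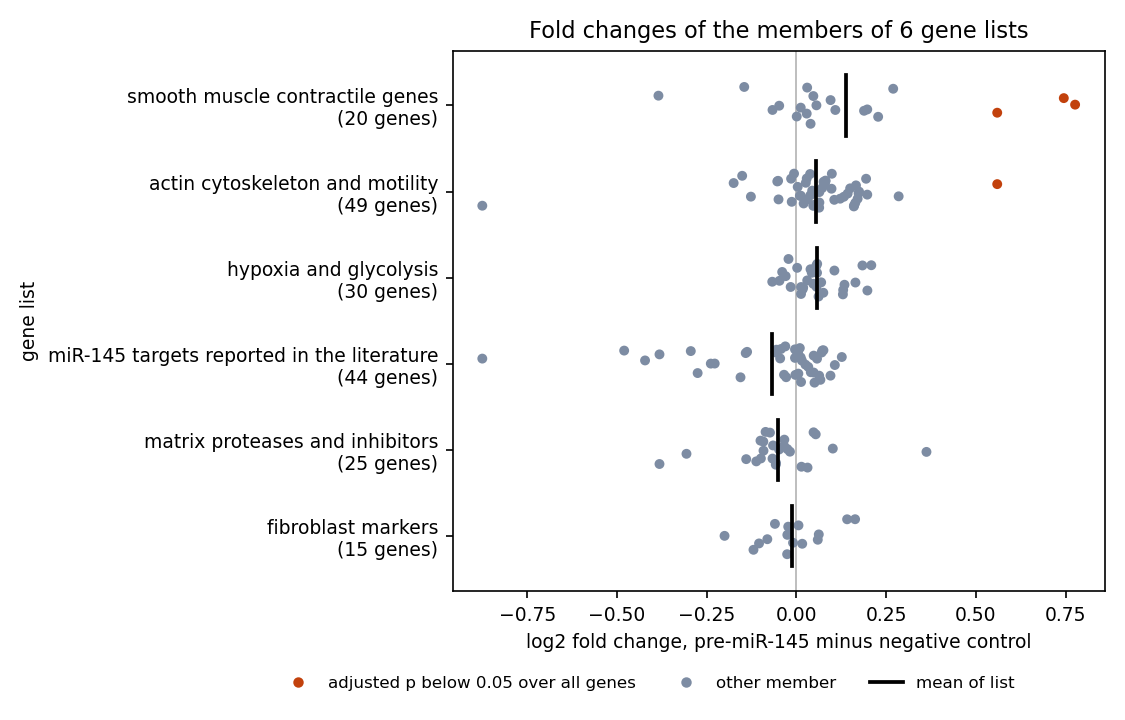
Log2 fold change of each measured member of 6 gene lists, pre-miR-145 minus negative control, with orange points for genes past the adjusted p threshold over all genes, grey points for other members and a black bar for the mean of the list. The mean of the 20 smooth muscle genes is 0.14, with *ACTG2*, *TAGLN* and *MYL9* at its upper end, and *FSCN1* at −0.87 is the lowest member of both the actin and the target list.

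The 25 matrix proteases and inhibitors were lower as a list, with 19 members below 0, a mean log2 fold change of −0.051 and a camera adjusted p of 0.0358. The adjusted p was 0.825 with an estimated correlation. No member passed over all genes or adjusted over the list alone in limma, and 2 lower and 1 higher member had an unadjusted p below 0.05. The smallest p-values belonged to *TIMP3*, an inhibitor of metalloproteinases, with a log2 fold change of 0.36, and *ADAM17*, a sheddase, with −0.38. Hypoxia and glycolysis genes were higher as a list, with 24 of 30 members above 0, a mean of 0.056 and a camera adjusted p of 0.0358, or an adjusted p of 0.848 with an estimated correlation. No member passed either adjustment in limma, and 1 was higher at an unadjusted p below 0.05. The glucose transporter gene *SLC2A1* had a log2 fold change of 0.21 and *ADM*, the adrenomedullin gene, 0.13. The protease list had a mean of −0.025 and an adjusted p of 0.529 without control replicate 1, and lost its call without pre-miR-145 replicates 2 and 3 (adjusted p of 0.162 and 0.106, at means of −0.046 and −0.042). The hypoxia list had a mean of −0.00069 and an adjusted p of 0.916 without control replicate 3, and lost its call without pre-miR-145 replicates 2 and 3 (adjusted p of 0.162 and 0.0966, at means of 0.047 and 0.059). With the *ACTB* covariate the mean of the hypoxia list was 0.021 and its adjusted p 0.732.

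The other 23 lists did not pass with camera, with fry or with an estimated correlation. Adjusted over the list alone, 1 gene each passed among the cell junction genes (*CLDN1*, a tight junction claudin, log2 fold change 0.36), the interferon response genes (*GBP1*, an interferon-induced GTPase, 0.35) and the stress response genes (*PSAT1*, an enzyme of serine synthesis, −0.40), and none of these passed over all genes. The second smallest p-values in these lists were those of *NECTIN3* (0.17), *IFIT2* (0.24) and *EDEM1* (−0.20). The camera adjusted p was 0.588 for cell junctions, 0.144 for the interferon response and 0.619 for the unfolded protein and integrated stress response. Without control replicate 1 the interferon list had a mean of 0.061 and an adjusted p of 0.0162, against a mean of 0.034 with all arrays. Without control replicate 3 its mean changed sign to −0.011, with a camera adjusted p of 0.877.

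In the remaining 20 lists no member passed over all genes or adjusted over the list alone in limma, and the values that follow are the log2 fold changes of the members with the smallest p. Among lists of matrix and cell identity, *CCN2* (0.28) and *THBS1* (0.25) led matrix adhesion and integrins, *ZEB1* (0.21) and *GRHL2* (−0.21) the epithelial-mesenchymal transition, *ERBB3* (−0.17) and *TFF1* (−0.17) the luminal markers, and *KRT14* (−0.20) and *SFN* (−0.084) the basal markers. Their camera adjusted p-values were 0.767, 0.797, 0.404 and 0.527. Among lists of the cell cycle and cell death, *CCNE2* (0.32) and *LIG1* (−0.17) led S phase and DNA replication, *HMMR* (−0.17) and *BUB1B* (−0.15) mitosis, *TIGAR* (0.19) and *POLH* (0.15) the p53 targets, and *BIRC2* (−0.19) and *BID* (0.18) the apoptosis regulators. The adjusted p-values of these lists were 0.619, 0.404, 0.626 and 0.536. In the histone list, with an adjusted p of 0.105, *H2AC6* was at 0.32 and *H2AX* at −0.21.

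Among the signalling lists, *IL11* (−0.20) and *CCL5* (−0.10) led NF-kB and inflammatory cytokines, *SHC1* (0.17) and *IGFBP3* (−0.26) insulin and IGF signalling, *DUSP5* (−0.25) and *FOSL1* (−0.28) receptor tyrosine kinase and MAPK signalling, and *ID3* (0.27) and *INHBA* (0.24) TGF-beta signalling. Their adjusted p-values were 0.101, 0.767, 0.404 and 0.382. Without control replicate 3 the NF-kB list had a mean of −0.073 and an adjusted p of 0.00339, against a mean of −0.039 with all arrays, and the MAPK list −0.056 and 0.0354, against −0.020. Without control replicate 1 the NF-kB list had −0.011 and 0.608, and the MAPK list 0.012 and 0.753. With the *ACTB* covariate their adjusted p-values were 0.00154 and 0.0244, at means of −0.067 and −0.051. In lists of metabolism and RNA, *LSS* (0.15) and *SC5D* (0.15) led cholesterol synthesis, *IPO4* (0.19) and *WDR74* (0.12) the MYC targets, *RPS6* (0.075) and *RPL18* (0.073) the ribosomal proteins, *PAN2* (−0.27) and *AGO2* (0.16) miRNA processing and silencing, and *PGK1* (0.16) and *HPRT1* (−0.10) the common reference genes. The adjusted p-values were 0.767, 0.504, 0.742, 0.695 and 0.585. Mean and median differed in sign for matrix adhesion and leukocyte markers, with means above 0, and for insulin signalling and the stress response, with means below 0. The camera direction followed the mean.

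The fibroblast and leukocyte markers did not shift as lists. Without expression levels, which of these genes the line itself expresses is unknown. The 15 fibroblast markers had a mean log2 fold change of −0.013 and a camera adjusted p of 0.536, with *COL1A1* at −0.20 and *COL5A1* at 0.16. The 14 leukocyte markers had a mean of 0.013 and an adjusted p of 0.767, with *CD79A* at −0.19 and *LCP1* at 0.37.

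Control probe sets differed between arrays in ways that partly followed the groups. The 12 probe sets for polyadenylated spike-in RNAs had a mean log2 difference of −0.47, pre-miR-145 minus control, and the groups did not overlap, with 0.10, 0.058 and 0.63 on the control arrays and −0.33, −0.025 and −0.27 on the pre-miR-145 arrays. This difference accompanied the contrast for every gene and list above. The difference between the 3′ and 5′ probe sets of *ACTB*, a measure of RNA integrity and labelling, was −0.45, 0.35 and 0.61 on the control arrays and 0.021, −0.017 and −0.38 on the pre-miR-145 arrays, which overlap. With this difference as a covariate, chosen after seeing the data, 4 genes passed, *ABHD17C*, *ABRACL*, *ACTG2* and *TAGLN*. Control replicate 3 stood apart, with a value spread (SD over all probe sets) of 0.223 against 0.112 to 0.162 on the other arrays and hybridization spike-ins at 0.56.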

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

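The covariate fit was chosen after seeing the data; the other settings had been set beforehand. Of these, some were not run: the brightest probe set per gene and both filters on dim genes need expression levels, and the seed match settings need transcript sequences. Which genes lie near background is therefore unknown. The count of 7 genes was 6 with a 1.5-fold minimum, 1 at an adjusted p below 0.01, 7 with the robust setting, with array medians subtracted and with a further quantile normalization, and 6 with every probe set as a row. With a trend 10 passed (7 lower), and with array weights 18 (15 lower), both holding the 7. With the *ACTB* covariate 4 passed (2 lower). Without _x_at and _s_at probe sets 6 passed, 1 of them higher (*ACTG2*), 4 of these among the 7 and *EXOC2* and *GMFB* besides, which are named after their values were seen. There *TAGLN* reversed to −0.0097, and *FSCN1* and *UNG* had no probe set left. With each array left out, 1 to 5 genes passed (1 to 3 lower, 0 to 2 higher). The share of genes that do not overlap stayed between 9.98% and 11.1%.

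*FSCN1* passed with a trend (−0.87, adjusted p of 0.00726), with its probe set of smallest p (−0.86, 0.0276) and with array weights (−0.99, 0.00466). Elsewhere its adjusted p lay between 0.0679 and 0.689, and it was negative in every setting that measured it. Over 82 other genes followed, some of them not named in the text, 1157 values kept direction and side of the threshold, 43 lost a call, 14 gained one and 1 reversed.

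Of the lists called, 0 passed with an estimated correlation, where the means stay as they were and the adjusted p was 0.207 for smooth muscle (mean 0.137), 0.765 for actin (0.0556), 0.825 for the targets (−0.0670) and the proteases (−0.0510), and 0.848 for hypoxia (0.0563). With array weights 2 lists passed, smooth muscle and actin; the targets had a mean of −0.0779 (0.121), the proteases −0.0532 (0.132) and hypoxia 0.0280 (0.287). Without _x_at and _s_at probe sets 1 passed, the targets; smooth muscle had 0.0481 (0.385), actin 0.0331 (0.0992), the proteases −0.0572 (0.0975) and hypoxia 0.0774 (0.0782). Actin had 0.0298 with the covariate (0.0492). Hypoxia also lost its call with quantile normalization (0.0460, 0.0644) and with the covariate (0.0213, 0.732). The other 4 lists called passed with the covariate. With each array left out 2 to 6 lists passed. The means ranged from −0.0981 to −0.0401 for the targets, −0.0752 to −0.0250 for the proteases and −0.00069 to 0.0916 for hypoxia, the lowest of these without control replicate 3, which reversed it. Smooth muscle (0.129 to 0.142) and actin (0.0305 to 0.0823) kept their calls with each array left out.

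After the values were seen, single settings were followed only for the 5 lists called. Of the 23 others, 15 changed the sign of their mean in some setting, to at most 0.0331 in size and with 0 past the threshold, and 3 passed somewhere. NF-kB and receptor tyrosine kinase and MAPK signalling both did without control replicate 3 and with the covariate. NF-kB also did with quantile normalization and, like the interferon response, with every probe set, and the interferon response without control replicate 1.

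The values gave no clear sign that equal replicate numbers pair the arrays, though 3 arrays per group cannot exclude it. The deviations of same-numbered arrays from their group means correlated at −0.31, 0.12 and −0.14. Only the arrays numbered 2 correlated best with their own number. With the replicate number as a block 1 gene passed, *ABHD17C* (1 lower, 0 higher), and 3 lists, the targets (mean −0.0670, adjusted p of 0.0505) and the proteases (−0.0510, 0.0505) being the ones lost. The block also takes degrees of freedom. Beyond what the missing probe sets, arrays and degrees of freedom account for, the cause of these changes was not tested.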

Other observations

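After *FSCN1*, the 5 genes with the next smallest p-values, which did not pass the threshold, were lower with pre-miR-145. These were *SECISBP2*, which encodes a factor for selenocysteine insertion (log2 fold change −0.48), *GMFB*, a regulator of actin branches (−0.48), *TMEM9B* (−0.49), the lipocalin gene *LCN2* (−0.50) and the transcription factor gene *GLIS3* (−0.51), with adjusted p-values in limma from 0.159 to 0.183. They were chosen after their values were seen. With array weights all 5 passed the threshold, with a trend *SECISBP2* and *TMEM9B* did, and without _x_at and _s_at probe sets *GMFB* did, and none of them passed in the other settings run.

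Of the tests below, the comparison of genes past the threshold across splits of the arrays and the test of RNA quality by 3′ and 5′ control probe sets were planned; all others were chosen after the results were seen. The 6 arrays make 10 splits, too few for a share under 0.05. The real split had 7 genes past the threshold and the highest of the other splits 0, so that 1 of the 10 gave as many. For lists, 5 of the 10 splits, the real one included, gave at least the 5 lists of the real one, and the highest other gave 8. That split set control replicate 1 and pre-miR-145 replicates 2 and 3 against the rest and had 2237 genes at an unadjusted p below 0.05 against 934, which points to a structure of the arrays other than the groups. The *ACTB* 3′ minus 5′ difference sorts the arrays in the same way. It was −0.45, −0.017 and −0.38 on those 3 arrays and higher, at 0.021, 0.35 and 0.61, on the other 3. The *GAPDH* difference overlaps between these sides, with −0.028, 0.015 and −0.064 against −0.0012, 0.14 and 0.14. Whether RNA quality made this split was not tested. For genes on one side at p below 0.001, 2 splits, the real one included, reached its 25 lower genes, and the highest other had 32.

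A first pattern was the set of genes that changed. RNA quality as its cause would separate the groups by the *ACTB* 3′ minus 5′ difference, or that of *GAPDH*, which differed by −0.29 and −0.10 but overlapped between groups. The 7 genes were called by a test that favours a small spread within groups. A covariate fit could therefore move them little and cannot decide on RNA quality. With the *ACTB* difference as a covariate the log2 fold changes of the 7 genes and *FSCN1* kept 95.5% to 107% of their size. *UNG*, *PODXL* and *MYL9* ended at an adjusted p of 0.0682 there, with log2 fold changes of −0.76 ± 0.082, −0.60 ± 0.061 and 0.56 ± 0.061 (SE) against −0.79 ± 0.082, −0.63 ± 0.064 and 0.56 ± 0.060 before, as the covariate takes a degree of freedom. The lower poly-A spike-ins with pre-miR-145 follow the groups, so an effect of sample preparation that they mark stays open, as does the effect of miR-145 that the design names.

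A second pattern was the higher mean of the smooth muscle contractile genes, carried for the most part by *ACTG2*, *TAGLN* and *MYL9*. Among the 10 splits the real one alone gave a camera p as small for this list, 1 of 10, and the smallest of the others was 0.0480, with too few splits for a share under 0.05. RNA quality would shrink the log2 fold changes of *TAGLN*, *ACTG2* and *MYL9* once corrected, and the smallest was still 0.56 with the covariate. The spread of these genes within groups was small beside their fold changes, with SDs of 0.024 and 0.037 for *MYL9*. A slope fitted to so little spread could hardly have moved them, so this fit cannot decide on RNA quality. Fibroblasts among the cells would raise their markers together, yet the mean of the 15 markers plus 2 standard errors across genes was 0.036. These genes share the same arrays and are not replicates, so this bound leaves out the spread between arrays. Centring also left no levels to compare. A candidate explanation is a wider rise of serum response factor targets, tested on 24 such genes outside the smooth muscle and actin lists. Other lists hold 5 of these, and 2 (*EDN1* and *CCN2*) had been seen among the higher genes beforehand. Without *EDN1* and *CCN2* the other 22 had a mean log2 fold change of 0.085. Their camera p was 0.00127 at the preset correlation but 0.109 with an estimated correlation (1.96e-05 and 0.0345 for all 24). The test with an estimated correlation also has fewer degrees of freedom. This explanation therefore stays open, as do RNA quality, cross-hybridization and the effect of miR-145 itself. The call of *ACTG2* did not rest on _x_at or _s_at probe sets, while *TAGLN* and *MYL9* were not called without them.

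The last pattern was the higher mean of hypoxia and glycolysis genes. Per array the list mean was 0.032, 0.0047 and −0.15 on control replicates 1 to 3 and 0.0031, 0.037 and 0.013 on the pre-miR-145 arrays. Without control replicate 3 the shift was −0.00069, which follows from these means and is no separate test of that array as the source. With the *ACTB* covariate it was 0.021 (adjusted p of 0.732), and that array had the highest *ACTB* difference, so RNA quality stays open here. Whether that array differed in culture or in handling was not tested, and no biological explanation was tested.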
